A study of Mus musculus with 2 samples.

How the data were processed

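The series measured H3K36me3 by ChIP-seq in hindbrain dissected from B6NCrl mouse embryos at embryonic day 12.5, with fragments of 300 to 500 bp per the labels. There were 2 samples in 1 group, biological replicates 1 and 2 per the labels, made from separate pools of 120 and 88 embryos of both sexes. Replicate 1 had 1 technical replicate and replicate 2 had 2, pooled by the authors before peaks were called.

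The authors deposited 4 peak lists in narrowPeak form on mm10, per the text files deposited with the samples. There was a list per replicate, a list from both replicates' alignments together, and a list of replicated peaks derived from the other three. All 109025 replicated peaks had the coordinates of a pooled peak, 76.5% were overlapped by both replicates' own lists and 52.4% were at least 50% covered by each. The aligner, the peak caller, its settings and the rule for replication are not given in the sources used here. The derivations recorded with the files name 2 control files for replicate 1, 1 for replicate 2, which replicate 1 also used, and 2 for the pooled list. The fold enrichment of a peak over control is a linear ratio deposited by the authors, and it was used only to describe, rank or weight peaks within a list. The deposited −log10 p and −log10 q values of each peak came from the same lists. The lowest −log10 p was 2.01 in replicate 1 and 2.03 in replicate 2, and the lowest −log10 q was 0.633 and 0.494, so the lists hold weak calls. No read counts or signal tracks were used, so depth is unknown, and a list's length cannot be separated from its depth or its control. The precision of each value is the SD over the replicates' own lists (n = 2). Values from the pooled and replicated lists are the authors' and have no SD.

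Peaks were compared with the GENCODE M21 annotation, which is on the same assembly (chromosome 1 has 195471971 bp in both). Overlapping peaks were merged. Each base of chromosomes 1 to 19 and X outside assembly gaps was given to the first feature that applied. The order was coding exon, 5' UTR, 3' UTR, other exon, intron, promoter (1 kb upstream of a transcript start) and intergenic. Promoter sequence inside a gene was therefore counted with that gene. A gene's coverage was the percent of its annotated span inside peaks, and a gene with at least 10% covered by replicated peaks was called marked. The main count took protein-coding genes of at least 2 kb; profiles in 10 equal parts took marked genes of at least 5 kb, each list over the genes it marked. Spans can overlap, and where a named gene lies inside another the coverage cannot be given to either. Peaks are narrow and were called without strand, so a short gene next to a marked gene can be covered by its neighbour's peak.

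Gene lists were matched on symbol among 21728 protein-coding genes. Of the 26 lists, 20 were written out and 6 were name patterns; 2 older symbols of the H3K36 methylation list and 6 noncoding imprinted genes were not among them. For each list the number of marked members was placed among 10000 random lists of the same size, drawn from all protein-coding genes in 20 length bins. Alternatives that change which genes can be drawn used 2000 random lists, drawn with replacement where a length bin held too few genes. The percentiles describe these libraries and are not tests. Peaks were placed at random 20 times within their chromosomes and outside assembly gaps.

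Named genes followed a rule written before the data were examined. It took the 10 genes with the highest enrichment density among genes of at least 10 kb that were marked in both replicates and overlapped no other protein-coding gene, and the 5 with the most base pairs covered. It further took the 5 longest without any peak, the 2 highest and the lowest member of each list by replicated coverage (the longer gene first in ties), and the 5 with the largest difference between replicates. It also took Setd2, Nsd1, Hoxa2, Hoxb1, Egr2, Mafb, Sox2, Tubb3, Atoh1 and Foxg1, and the 5 longest runs of peaks at least 10 kb from any gene. Other genes were named after their values were seen, among them the highest peaks, the X genes, Hoxb2, Meis2, Mog, Slc7a10, the lincRNA genes and the single-exon genes named.

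The steps were checked on simulated peaks planted in 200 genes. The largest error of coverage was 0.00942 percentage points, 147 of 147 genes planted at 20% or more were called marked and 0 of 53 planted at 5%. Of 200 random lists of genes, 7 lay above all but 2.5% of their matched lists. Alternatives covered the peak list, each replicate's own list, thresholds on −log10 q, joining of peaks across gaps of up to 1 kb, coverage thresholds of 5%, 20% and 50%, gene length filters, overlapping genes and the overlap that counts as shared. Peaks on the Y chromosome and on unplaced contigs entered no comparison. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, bedtools 2.31.1 and matplotlib 3.10.9.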

Results

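H3K36me3, a trimethylated form of histone H3 that lies along the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing in mouse hindbrain, the part of the embryonic brain that forms the cerebellum, pons and medulla. The tissue came from B6NCrl embryos of both sexes at embryonic day 12.5. There was 1 group with 2 biological replicates, a pool of 120 embryos in replicate 1 and a pool of 88 embryos in replicate 2. The values were lists of enriched regions (peaks) on the mm10 assembly. Replicate 1 had 186111 peaks covering 102 Mb, and replicate 2 had 149690 peaks covering 70.2 Mb, so that the replicates' own lists averaged 86.3 ± 22.7 Mb (SD, n = 2). A list called on both replicates together held 186899 peaks, of which 109025 (58.3%) were kept by the authors as replicated peaks. These replicated peaks covered 108 Mb, or 4.20% of the assembled sequence of chromosomes 1 to 19 and X. Read depth is unknown, because the lists give no read counts. With a single group, the comparisons are between parts of the genome, genes and gene lists, and between the replicates. No p-value was computed across peaks or genes, which are not replicates.

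Peak sequence lay mostly inside genes, and coding exons were the feature most enriched over their share of the genome. Annotated genes make up 47.3% of the genome but held 95.4% ± 0.378 (SD, n = 2) of the peak sequence of the replicates' own lists, and protein-coding genes alone held 94.5% of the replicated peak sequence. Coding exons were the most enriched feature, at 8.67 ± 0.882 times their share of the genome (SD, n = 2). The 3' UTRs stood at 5.75 ± 0.207 times and other exons at 3.30 ± 0.101 times. With the annotation limited to protein-coding genes, other exons rose to 7.03 in the replicated list, above the 3' UTRs at 5.77. Introns took 69.0% ± 1.32 of the peak sequence, 1.63 ± 0.0311 times their genomic share. Promoters, taken as the 1 kb upstream of a transcript start where it lies outside every annotated gene, were depleted to 0.131 ± 0.0108 times. The remaining intergenic sequence was depleted to 0.0856 ± 0.00709 times. The 5' UTRs stood at 1.35 ± 0.0415 times, far below the 3' UTRs. In the replicated list the corresponding values were 8.01 for coding exons, 5.76 for 3' UTRs, 1.65 for introns, 0.135 for promoters and 0.0859 for intergenic sequence. The gaps between coding exons, introns and promoters were larger than the SD of the replicates for each feature. These shares pool all genes, marked or not, so they also reflect which genes and which parts of genes were marked. Exons and introns were not compared within marked genes.

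**Figure D1:**
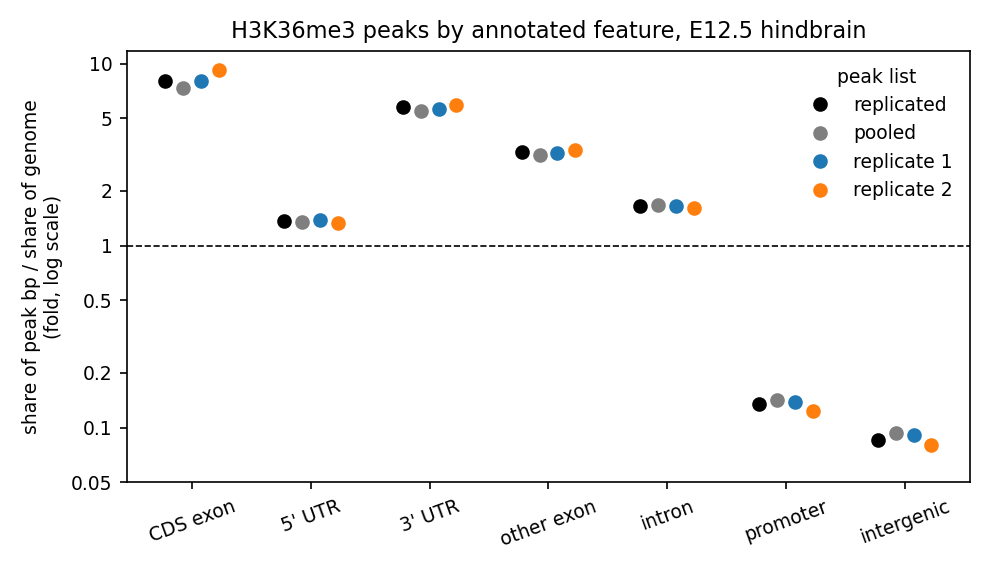
Share of peak base pairs divided by share of the genome (log axis) for 7 annotated features, with 1 point per peak list. Coding exons reached 8.01 and promoters 0.135 in the replicated list, and the dashed line at 1 marks the genomic share.

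Within marked genes the coverage rose from the start towards the end. Among the 7234 protein-coding genes of at least 5 kb that were at least 10% covered by replicated peaks, the first of 10 equal parts of the gene body was 5.03% covered on average, the fifth 45.8% and the ninth 63.0%. Coverage was 59.9% in the last part. The last 5 parts were covered 2.08 times as much as the first 5, and 6359 genes (87.9%) had more coverage in the last 5 parts. In the replicates' own lists, each over the genes it marked, this ratio was 2.13 ± 0.113 (SD, n = 2).

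**Figure D2:**
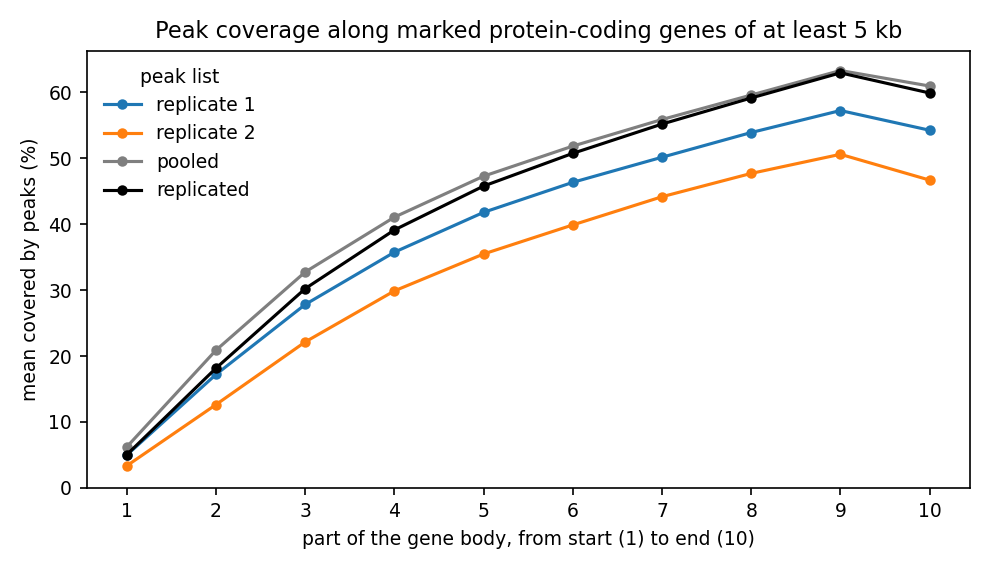
Mean percent of sequence covered by peaks in 10 equal parts of the gene body, from start to end, for each of the 4 peak lists over the genes it marks. All 4 curves start below 7% and peak in part 9, where the replicated list reaches 63.0%.

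A minority of protein-coding genes carried the mark over an appreciable part of their length. Of 20176 genes of at least 2 kb, 7880 (39.1%) were at least 10% covered by replicated peaks and are called marked here, and 9686 (48.0%) had no replicated peak at all. At least 50% covered were 2894 genes by replicated peaks, 2343 in replicate 1's own list and 1238 in replicate 2's. The replicates' own lists marked 7322.5 ± 940 genes (SD, n = 2), or 36.3% ± 4.66. Random placement of the replicated peaks within their chromosomes marked 2455 ± 45.5 genes (SD over 20 placements). Genes of 20 to 100 kb were marked most often, at 48.4%, against 25.8% of genes of 2 to 5 kb and 2.83% of the 566 genes longer than 300 kb. Of these longest genes 2.47% were marked in replicate 1's own list and 0.530% in replicate 2's. The 10% threshold asks for more base pairs in longer genes, so an unmarked long gene can still hold long stretches of peaks. Ank3 (628666 bp) and Ank2 (577739 bp), picked after their values were seen, were 9.67% and 9.26% covered by replicated peaks.

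Zinc finger genes were frequent among the genes with the densest enrichment, making up 19 of the 100 densest genes of at least 10 kb and 342 of all 14049 such genes. Density was the sum of the authors' fold enrichment times overlapped base pairs, divided by gene length. Among genes of at least 10 kb that overlap no other protein-coding gene, the 10 densest were Zfp90, Zfp68, Zfp110, Zfp606, Kmt2d, Bag6, Chd4, Zfp810, Zfp334 and Exosc10, 6 of them zinc finger genes. Zfp90 (chromosome 8, 106415327 to 106426598, plus strand) had a density of 9.18 and was 82.4% covered by replicated peaks and 81.6% ± 3.56 covered in the replicates' own lists (SD, n = 2). Kmt2d, which encodes a histone H3 lysine methyltransferase of enhancers, was 83.6% ± 2.00 covered (chromosome 15, 98831669 to 98871204). Chd4, the remodelling ATPase of the NuRD complex, was 79.9% ± 7.34 covered (chromosome 6, 125095981 to 125130591). Exosc10, a nuclease of the RNA exosome, was 85.2% ± 1.65 covered. Bag6, a chaperone of newly made membrane proteins, was 73.7% ± 2.41 covered. In all 4 lists the peak with the highest deposited −log10 q lay in the 3' part of Zfp810. The replicated peak there spans 22276335 to 22281186 on chromosome 9 with a fold enrichment of 16.4, and its 4852 bp hold 1160 bp of coding exon, 1480 bp of 3' UTR, 1799 bp of intron and 413 bp beyond the gene.

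**Figure D3:**
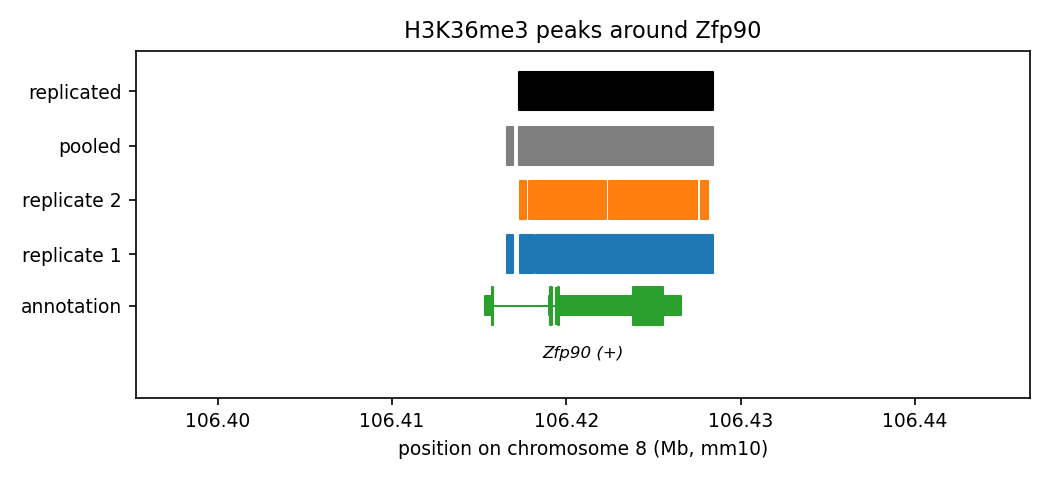
Map of Zfp90 and 20 kb on either side on chromosome 8 (mm10, Mb), with annotated exons (tall, coding; low, other) and the peaks of each list as blocks. The longer replicated peak starts inside the gene at 106417314 and runs past its annotated end at 106426598, and a shorter one ends at 106428410.

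By covered length the first genes were Gm20388 (582 kb covered) and Fgfr2 (203 kb), whose annotated spans of 4.43 Mb and 2.96 Mb run over many other genes. Outside those genes only 0.911% of Gm20388 and 1.56% of Fgfr2 was covered. Next came Syne2, a nuclear envelope linker protein, with 138 kb covered, 37.1% ± 9.23 of its length in the replicates' own lists. Wdfy3, an autophagy scaffold, had 128 kb covered, 45.9% ± 8.04. Ubr4, a ubiquitin ligase, had 121 kb covered, 81.8% ± 5.36. The longest genes without overlap with any peak of the 4 lists were Dmd (2257 kb), Lsamp (2197 kb), Fhit (1612 kb), Ctnna3 (1574 kb) and Pcdh15 (1550 kb). Setd2, the main H3K36 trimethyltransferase, was itself 35.9% ± 8.19 covered (chromosome 9, 110532597 to 110618633) and Nsd1, an H3K36 dimethyltransferase, 46.4% ± 9.94 (chromosome 13, 55209782 to 55318325). Tubb3, the neuronal beta tubulin, was 34.3% ± 5.84 covered (chromosome 8, 123411424 to 123422015), although its span lies wholly inside that of Gm20388. Hoxa2, Hoxb1, Egr2, Mafb, Sox2, Atoh1 and Foxg1 had 0% in all 4 lists.

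Gene lists written before the data were examined differed widely in how many of their members were marked. Of the 26 lists, 6 had more marked members than all but 2.5% of 10000 length-matched random lists, 16 had fewer than all but 2.5%, and 4 lay between. The highest and lowest members named are those by replicated peaks, with their mean over the replicates' own lists where an SD is given. All 32 cell cycle genes were marked in the replicated list (random lists 14.3 on average), 31 in replicate 1 and 29 in replicate 2. The replication helicase genes Mcm5 and Mcm2 were 60.9% ± 7.96 and 61.5% ± 10.4 covered in the replicates' own lists (SD, n = 2), and the lowest member, Pcna, the sliding clamp of replication, was 6.50% ± 9.19. Among housekeeping genes 27 of 30 were marked (random 12.2), with Eef2, a translation elongation factor, at 78.0% ± 4.28 and the chaperone gene Hsp90ab1 at 73.3% ± 0.656. Hprt, a purine salvage enzyme on the X chromosome, was the lowest member at 2.27% ± 0.221. Ribosomal protein genes were marked in 63 of 79 cases (random 19.2), led by Rps15a at 66.9% ± 7.95 and Rps28 at 62.7% ± 7.94. Only 29.7% of Rps28 lies outside Kank3, and that part was 31.2% covered by replicated peaks. Rpl3l, a muscle paralog, had 0%. Writers, erasers and readers of H3K36 methylation were marked in 21 of 24 cases (random 10.3), led by the demethylase Kdm4a at 85.2% ± 3.92 and Brd1 at 68.6% ± 7.82. Phf19, a Polycomb-associated reader, had 0%. The zinc finger list had 295 of 424 members marked (random 185), with a median coverage of 24.2% ± 4.91 in the replicates' own lists. Zfp869 reached 90.2% ± 1.71 and Zfp335 84.9% ± 2.74, whereas the 576 kb gene Zfp804b had 0%.

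Neuronal genes were marked more often than random lists, and neural progenitor genes were not. Of 38 neuronal genes, 18 were marked (random 11.2), with Tagln3 at 53.9% ± 6.59, Myt1, a transcription factor of new neurons, at 36.1% ± 11.6, and the axon guidance receptor Robo2 at 0% in the replicated list. With replicate 2's own list 12 members were marked (random 8.71, percentile 90.9), which is no longer above all but 2.5% of random lists. Of 26 neural progenitor genes 10 were marked (random 8.41). Msi1, an RNA-binding protein of stem cells, was 65.3% ± 10.4 covered and Vim, the intermediate filament vimentin, 39.8% in replicate 1 and 40.3% in replicate 2, while Sox1 had 0%.

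Transcription factors that pattern the hindbrain were rarely marked. Of 44 such genes 3 were marked by replicated peaks (random 13.4), 4 in replicate 1 and 0 in replicate 2. Meis1, a Hox cofactor, was 10.9% ± 3.85 covered, Irx1 6.74% ± 5.39 and Meis2 8.52% ± 5.24, and Pax5 had 0.428% ± 0.271. None of the 15 Hox genes of groups 1 to 5, which are used in the hindbrain, was marked by replicated peaks (random 4.77), including the longest, Hoxc5 and Hoxa3. Of the 8 that overlap no other protein-coding gene 0 were marked as well (random 1.82), which with so few members is no longer below all but 2.5% of random lists (percentile 5.60). Hoxb2 was 10.7% covered in replicate 1's own list and 0% in replicate 2's. None of the 16 Hox genes of groups 9 to 13, used in the trunk and limbs, was marked either (random 4.47), Hoxa10 and Hoxc9 among them. No forebrain transcription factor of 22 was marked (random 7.88); Bcl11b came highest at 4.26% ± 1.21, and Satb2 had 0% in the replicated list.

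Markers of other cell types were mostly unmarked. The erythroid, endothelial, mesenchyme and mural, choroid plexus, and microglia and macrophage lists stand for types that dissected hindbrain at this stage can hold. The oligodendrocyte, astrocyte, liver, muscle and germ line lists stand for types it should largely lack. Of 20 erythroid genes 1 was marked (Nfe2, 14.5% in replicate 1 and 11.5% in replicate 2), of 20 endothelial genes 1 (Mfsd2a, the lipid transporter of brain vessels, 29.4% ± 10.5) and of 20 mesenchyme and mural genes 1 (Fn1, fibronectin, 44.4% ± 8.63), against 6.38, 7.31 and 8.57 in random lists. Alas2 (wholly inside Apex2), Eng and Pdgfrb came next in these lists by replicated peaks, at 5.52%, 0.954% and 8.81%. In the choroid plexus list 1 of 14 was marked, Kcnj13 at 17.2% ± 8.44, which lies wholly inside Gigyf2. In the microglia and macrophage list 2 of 18 were marked (random 6.32). Cd68, at 68.7% ± 9.40, is 1.94 kb long and lies less than 1 kb from Eif4a1, and the part of Cx3cr1 outside other protein-coding genes had 0%. With replicate 2's own list 2 microglial genes were marked (random 5.18, percentile 4.13), no longer below all but 2.5% of random lists. Among 15 oligodendrocyte genes 3 were marked by replicated peaks (random 6.94) and 1 in each replicate's own list, Cnp at 72.1% ± 4.32, Myrf at 6.12% ± 4.61 and Mog at 9.06% ± 1.29, whereas Mbp, a myelin protein, had 0% in the replicated list. The authors' pooled list raised that count to 4 (random 7.50, percentile 3.81). Of 12 astrocyte genes 3 were marked (random 4.86, percentile 14.3), which is not below all but 2.5% of random lists. They were Fgfr3 at 36.6% ± 14.7, Aldoc at 10.6% ± 5.82 and Slc7a10 at 11.2% ± 2.17. Only replicate 2's own list, with 1 astrocyte gene marked, placed it below all but 2.5% of random lists (percentile 2.27). None of the 21 liver, 20 skeletal and cardiac muscle or 18 germ line genes was marked, against 8.43, 7.06 and 7.68 in random lists. Hnf1a led the liver list at 4.15% ± 0.227, Ttn and Mybpc3 had 1.08% ± 0.315 and 0.438% ± 0.620, and Sycp1 had 0%.

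Receptor genes of the olfactory and vomeronasal systems and histone genes were unmarked. None of 1134 olfactory receptor genes was marked (random 341), nor any of 328 vomeronasal receptor genes (random 117), Vmn2r7 and Olfr56 being the longest. None of 67 replication-dependent histone genes was marked (random 5.58), though these genes are used in dividing cells. Clustered protocadherin genes were marked in 22 of 56 cases (random 15.6), led by Pcdhga3 at 38.6% ± 6.66 and Pcdhga2 at 38.0% ± 6.25. Those members share most of their span and are not independent, and replicate 2's own list placed their count of 21 at percentile 99.9, above all but 2.5% of random lists. Imprinted genes were marked in 8 of 21 cases (random 7.76), Nnat at 75.5% ± 8.99 inside Blcap and Igf2r at 45.2% ± 10.2, while Igf2 had 0%.

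**Figure D4:**
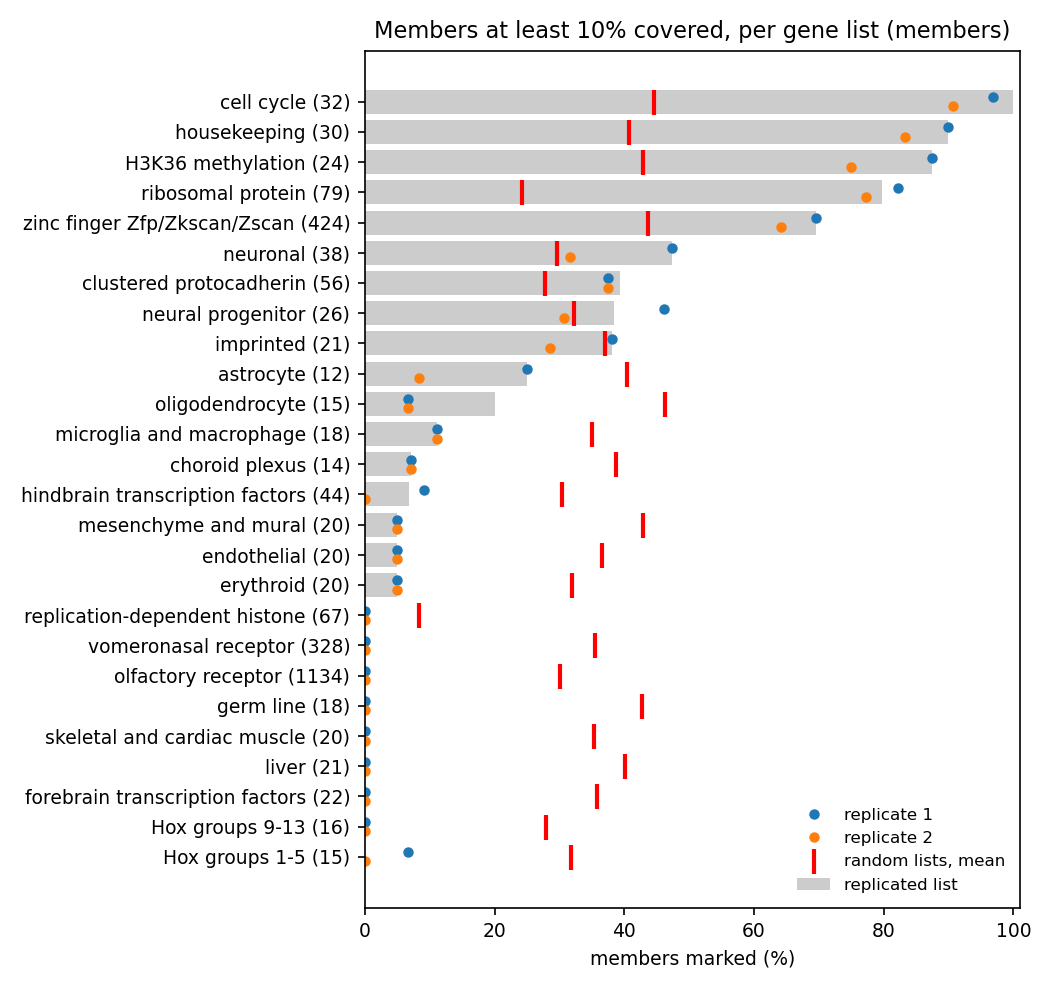
Percent of members at least 10% covered for each of the 26 gene lists (number of members in brackets), as bars for the replicated list and points for each replicate's own list. Red ticks give the mean percent of 10000 length-matched random lists; all 32 cell cycle genes and none of the 21 liver genes were marked.

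Genes on the X chromosome were marked far less often than autosomal genes. On X 96 of 791 genes (12.1%) were marked by replicated peaks, against 40.2% of autosomal genes, with a range over the 19 autosomes from 29.6% on chromosome 14 to 50.6% on chromosome 8 and an SD of 5.25. Over the replicates' own lists the X value was 10.3% ± 4.56 (SD, n = 2). Replicate 2 alone gave 7.08% on X and 34.1% on autosomes, and replicate 1 alone 13.5% and 40.7%. In every list X lay below the lowest autosome. The X genes with the highest density, picked after their values were seen, were Flna, an actin crosslinker, at 58.9% ± 11.4 covered, Maged1 at 50.4% ± 6.25, Kdm5c, a histone demethylase, at 45.9% ± 12.4, and Hcfc1 at 50.7% ± 10.5.

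**Figure D5:**
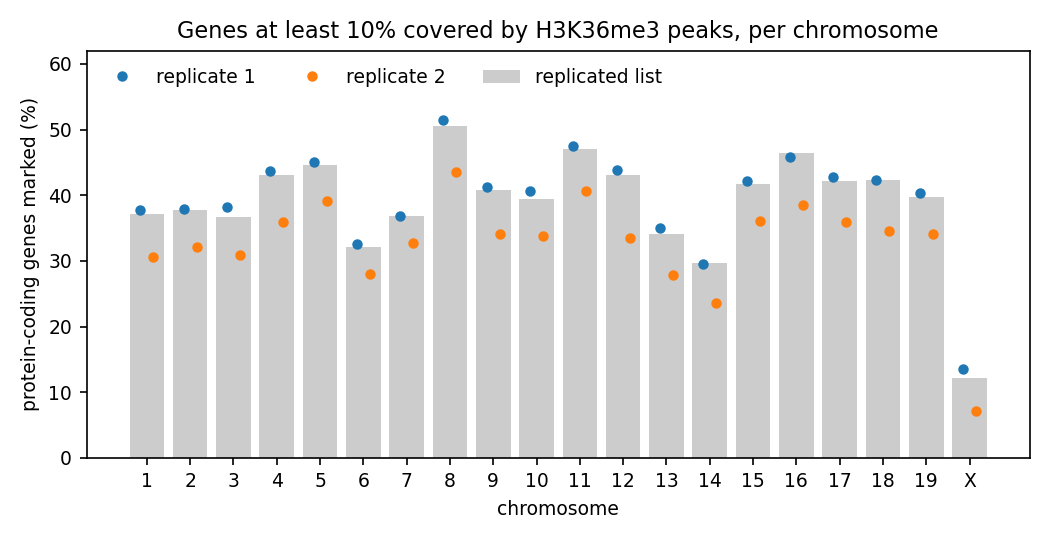
Percent of protein-coding genes of at least 2 kb that were at least 10% covered, per chromosome, with bars for the replicated list and points for each replicate's own list. X stands at 12.1%, below chromosome 14, the lowest autosome at 29.6%.

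The replicates gave most genes the same call and differed in how much of each gene was covered. Across genes, which are not independent, the percent of the gene body covered in replicates 1 and 2 had a Spearman correlation of 0.961 and a Pearson correlation of 0.976. Both marked 6637 genes and neither marked 12168, so that 93.2% of genes had the same call, most of them as unmarked. Genes without a peak, 8589 in replicate 1's own list and 9638 in replicate 2's, also entered the correlations. Replicate 1 alone marked 1350 genes and replicate 2 alone 21. Coverage was higher in replicate 1 for 11158 genes and in replicate 2 for 572. The largest differences lay in the short genes Dnd1 (62.7% against 15.6%), Kcnk7, Tmem101, Tas1r3 and Fgf22, with an SD of 28.3 points or more. Of replicate 1's peaks, 43.5% had at least 50% of their length in replicate 2's peaks, and 77.2% of replicate 2's peaks lay in those of replicate 1. Random placement gave 2.99% ± 0.0383 and 4.48% ± 0.0511 (SD over 20 placements). Shared peaks of replicate 1 had a median deposited fold enrichment of 3.62 and a median width of 503 bp, against 2.87 and 272 bp for those not shared. Both lists were called against a control they had in common, and replicate 1 also against a second control, so part of the overlap and of the difference between the lists can come from the controls.

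Peaks far from genes were few. Of 21664 runs of replicated peaks joined across gaps of up to 3 kb, 62 (0.286%) lay at least 10 kb from any gene of the GENCODE annotation. The longest measured 7.32 kb (chromosome 4, 91222191 to 91229507) and was 67.1% covered in replicate 1 and 26.0% in replicate 2. A run of 6.24 kb followed on the same chromosome (91211114 to 91217354). RefSeq places both in Elavl2, a neuronal RNA-binding protein, and places a run of 6.22 kb on chromosome 5 (104582142 to 104588364) in Zfp33b. The remaining long runs, of 3.05 kb on chromosome 19 (60179475 to 60182524) and 2.59 kb on chromosome 2 (84576409 to 84578997), overlap no RefSeq gene.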

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

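Signal outside the main comparisons was set against the limit of 3 that a count of 0 allows, since no control samples were at hand. That limit takes no account of background, so a count above it does not show a signal above background. On the Y chromosome the replicated list held 8 peaks, as did each of the other lists. A single peak, at 1278324 to 1278726, lay in Ddx3y, an RNA helicase gene, with a fold enrichment of 3.02, and the others lay between 90724023 and 90745892, where no gene is annotated. Unplaced or unlocalized contigs held 8 replicated peaks on 5 contigs, 27 in replicate 1's own list and 15 in replicate 2's. Among 4009 lincRNA genes of at least 2 kb outside protein-coding genes, 56 (1.40%) were marked by replicated peaks, and 51.5 ± 16.3 in the replicates' own lists (SD, n = 2). Random placement of the peaks marked 496 ± 26.2 of them (SD over 20 placements, highest 542). These lincRNA genes were chosen outside protein-coding genes, which held 94.5% of the replicated peak sequence. Random placement moved peaks out of protein-coding genes, so the lower observed count was set by that choice and shows no depletion of lincRNA genes.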

How the results depend on the processing

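The comparison with random lists drawn without receptor genes and the one without overlapping genes were chosen after seeing the data. Coding exons remained enriched, the ends of genes more covered than their starts, and X below the autosomes under each alternative run, and no direction reversed. Without replicate 1 or without replicate 2, genome coverage ranged from 70.2 to 102 Mb, coding exon enrichment from 8.04 to 9.29 times, the ratio of the last to the first 5 parts from 2.05 to 2.21, and the ratio of X to autosomal marked shares from 0.208 to 0.333. The share of replicate 1's peaks found in replicate 2 was 57.6% with an overlap of 1 bp, 21.9% with 80% of the peak, 42.7% at a −log10 q of at least 2, 41.9% at 5, 49.4% with equal numbers of peaks and 32.8% with peaks joined across 1 kb. Joining also lowered coding exon enrichment to 7.01. The pooled list gave a position ratio of 1.97 and an X to autosome ratio of 0.393, and genes of at least 20 kb a position ratio of 1.91. A threshold of 50% marked 2894 genes, by construction fewer, and the share of marked genes ran from 14.3% there to 43.8% at a threshold of 5%. The Spearman correlation of the replicates was 0.958 and 0.916 at a −log10 q of at least 2 and 5, 0.964 with equal numbers of peaks and 0.956 with no minimum length. Apart from the stricter thresholds and filters, whose construction lowers the counts, the cause was not tested.

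The number of lists with more marked members than all but 2.5% of random lists was 6 under each alternative, though not always the same lists. Of the 26 lists 20 stayed on their side throughout and 6 did not, with 248 of 259 placements unchanged. The neuronal count no longer passed the upper bound in replicate 2's own list, at a −log10 q of at least 5 (14 marked, random 9.90, percentile 94.2) and at a 20% threshold (13 marked, random 8.17, percentile 97.4). The protocadherin count passed the upper bound in replicate 2's list, at a −log10 q of at least 5 and at a 20% threshold, and had no value without overlapping genes, since too few members were left. Without overlapping genes the counts of microglial genes (1 of 14 marked, random 3.88, percentile 2.70) and of Hox groups 1 to 5 (0 of 8, random 1.82, percentile 5.60) no longer passed the lower bound, with fewer members left. Astrocyte genes fell below the lower bound in replicate 2's list (percentile 2.27). For 105 named genes, 393 of 525 coverages under the 5 alternative lists were within 1 SD of the replicated value. Named genes at 0% in every list are counted there and agree by construction. The SD comes from the replicates' own lists, which are among the alternatives, so this count is no measure of stability. No paired analysis was possible because there is 1 group. Unknown depth limits every count: a gene without a peak may carry the mark below the detection limit, and replicate 2's list, which covers the fewest base pairs, marked 6658 genes where the pooled list, which covers the most, marked 8671.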

Other observations

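The test on the share of cells that use a gene was chosen after its result was seen, and the other tests were set out before theirs. Of 6 noncoding imprinted genes, Meg3, Rian and Mirg on chromosome 12 were marked by replicated peaks. Meg3 was 34.3% ± 15.2 covered in the replicates' own lists (SD, n = 2), Rian 16.9% ± 3.79 and Mirg 41.4% ± 7.14. The antisense imprinted RNAs Kcnq1ot1 and Airn had 4.33% ± 1.94 and 3.99% ± 1.18, and H19 had 0%. The coverage of Kcnq1ot1, which lies wholly over Kcnq1, and of Airn, which lies partly over Igf2r, cannot be given to either strand. Rmst, a neural lincRNA picked after its value was seen, had 10.7% ± 6.34.

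Housekeeping and ribosomal genes on the X chromosome lay below the autosomal median of their lists. By replicated peaks, Pgk1, a glycolytic enzyme, was 21.7% covered (13.2% ± 11.8 in the replicates' own lists) and Hprt 3.90%, and the autosomal housekeeping genes had a median of 54.1%. Among ribosomal genes Rps4x was 21.6% covered by replicated peaks (8.13% ± 11.5 in the replicates' own lists) and Rpl10, Rpl39 and Rpl36a 0%, with an autosomal median of 49.2%. Some autosomal members lay lower than Pgk1 and Rps4x, such as Eef1a1 at 7.69% and Rpl3l at 0%.

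The low share of marked genes on X was weighed against 3 explanations. Gene families unused in this tissue would leave the remaining X genes covered like autosomal genes, but X genes with a replicated peak had a median coverage of 7.14%, below the autosomal range of 21.6% to 37.5%, which argues against this as the whole cause. Against length and GC content as the whole cause, 96 X genes were marked where 1000 matched draws of autosomal genes gave 230 to 303. What stays open is signal near the detection limit: X peaks had a median width of 513 bp, below the autosomal range of 586 to 697 bp, and a median fold enrichment of 2.92, consistent with an X signal that often falls below the calling threshold. No biological explanation was tested, and the number of active X copies in pooled male and female embryos remains untested.

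The dense enrichment over zinc finger genes was weighed against shared reads and sequence content by the list's median density. A high median was not particular to zinc finger genes. The housekeeping, H3K36 methylation, ribosomal protein and cell cycle lists had higher medians, at 2.42, 2.12, 2.02 and 1.93, each at percentile 100 of length-matched lists. Zinc finger genes with no other member of the list within 200 kb, 147 in number, had a median density of 1.11. Length-matched lists averaged 0.0795, which put these genes at percentile 100. This argues against reads shared between neighbouring members of the list as the whole cause of the high median. The 277 zinc finger genes with another within 200 kb had a higher median of 1.32, so a contribution from such reads stays open. The list was a name pattern, so neighbouring paralogs under other names were not counted, and reads shared with them stay open. Matching on both length and GC content left the full list at percentile 100, with a median density of 1.21 against 0.0490. A list's median density depends on how many members were marked, which was already known (295 of 424, length-matched random lists 185). These comparisons therefore do not test why zinc finger genes were frequent among the 100 densest genes. Reads shared between distant paralogs were not tested and stay open. No biological explanation was tested.

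The scarcity of marked hindbrain transcription factor genes was weighed against gene length and GC content. The 3 marked members lay at percentile 0 of length-matched random lists (4 to 24 marked), which is how the scarcity was seen and is no separate test of short genes. Lists matched on length and GC content had 6 to 30 marked members, again percentile 0, which argues against length and GC content as the whole cause. The number of exons was not matched, although single-exon genes were marked less often than matched multi-exon genes, so its part stays open. Expression in part of the cells only cannot be told apart from the absence of the mark, because no expression per cell was measured. The cell cycle list, whose genes are used in the dividing cells, was marked in 100% of its members, but the share of cells using each factor is not known.

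A hypothesis was that genes without introns carry less of the mark than other genes of the same length and GC content. Of 1185 single-exon genes outside the olfactory, vomeronasal and histone families, 111 were marked, and 1000 sets of matched multi-exon genes had 206 to 259, which puts the count at percentile 0 and is in line with the hypothesis. Among the marked exceptions were Sox11, at 15.6% ± 10.4 in the replicates' own lists, and Fem1a, at 40.9% ± 11.9. Whether these genes are also less transcribed was not measured.

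A second hypothesis was that intergenic runs of peaks mark transcripts that RefSeq annotates and GENCODE M21 does not. Of the 62 runs at least 10 kb from any GENCODE gene, 20 overlapped a RefSeq gene, and 20 random placements in the same intergenic space gave 2 to 9. This goes with the hypothesis for part of the runs, and the others overlap no gene in either annotation. The count takes any overlap with a RefSeq gene span. A longer RefSeq form of a gene that GENCODE also holds is therefore not told apart from a transcript that GENCODE lacks. The placements also did not match the runs' distance to the nearest GENCODE gene.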
